A study of Mus musculus with 36 samples.

How the data were processed

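Transcript levels were measured on Illumina Mouse WG-6 BeadArrays in 30 LLC tumours and 6 arrays of LLC cells. Per the labels' protocols, RNA was extracted from pieces of tumour with TRIzol. The series text adds that column purification was an alternative, that RNA passed an integrity filter, and that it was amplified, labelled with biotin, hybridised and scanned. Intensity values and a detection p-value for each probe and array were deposited by the authors from GenomeStudio, per the file headers and the submitters' processing notes; its version is not given in the sources used here. The deposited intensity is the mean bead brightness on a linear scale, with no normalization between arrays and a lowest value of 66.6. A second deposited table holds the authors' normalized intensity, which the series text describes as rank variant normalization after a filter on detection. That wording leaves the method open, and no scale or floor is stated. Its columns ranked best with their own array's signal for all 36 arrays. Their medians ran from 134 to 183, the highest on a dim array, and were used only as an alternative.

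Samples were grouped by the age and treatment in the labels. Labels and files place the cell controls in a batch but give no chip or batch for any tumour, so tumours could not be compared within batches. The sample descriptions also number each tumour, in a separate series for each group. The series of the middle-aged unirradiated tumours lies furthest from the others. What the numbers stand for is not stated. Probes were named through the platform's probe table: 34807 probes matched through an entrez id and 0 symbols changed. Symbols can be old, and 10378 of the 45281 probes (22.9%) are not named here. Of 19057 genes with a probe, 9172 had several.

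Background was corrected by normexp with negative control parameters inferred from the detection p-values (neqc, offset 16), and all 36 arrays were quantile normalized together on the log2 scale. The brightest probe over the tumour arrays stood for its gene. Other detected probes of a gene could give another size of change, so the sizes given hold for that probe. Genes detected (p-value under 0.05) on at least 5 of the 30 tumours were tested, which left 10907; tumours against cells used at least 5 of 36 arrays and the control batches at least 3 of 6. Intensities near background are compressed, so log2 differences of dim genes understate the change. For a probe undetected on every array of a group, the fold is a bound: the bright group's mean against the mean, per array, of the higher of the lowest detected signal and the probe's own. A bound under 1 gives no fold. No bound was set for the difference between the irradiation effects, where values are plain log2 estimates.

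Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. All 30 tumours entered 1 fit of 4 group means. The contrasts were age in unirradiated and in irradiated mice, irradiation in young and in middle-aged mice, middle-aged irradiated against young unirradiated, and the difference between the irradiation effects. For tumours against cells the 6 control arrays were averaged to 1 sample.

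The comparisons, their alternatives, the rule for named genes and 36 gene lists (cell types, tissues beside a tumour and pathways, 766 entries, 691 with a probe) were chosen before the data were examined. The 34 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation and with fry. B and plasma cell markers and peripheral nerve markers had fewer tested members and were not tested. Lists overlap in places and are not independent.

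Named genes follow that rule. Where a comparison had 10 calls or fewer, all were named; where it had none, the 3 genes per direction with the smallest p were given as not passing. Up to 4 members with the smallest p were named per described list in tumour comparisons, 2 in the comparison with cells, where that number was set after the results were seen, which also names the 12 largest rises and 12 largest falls. Other genes are said to be chosen after their values were seen.

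The procedure was tested on simulated data with 100 genes changed by each size, on the scale of the tumours' spread. Of 100 genes changed by 1 on the log2 scale it recovered 92 with age in unirradiated mice, 89 with irradiation in young mice, 84 with irradiation in middle-aged mice, 35 between tumours and cells and 72 between control batches. Of 100 changed by 2 it recovered 100, 99, 98, 86 and 95. With a shift of 0.5 camera recovered 32 of 34 lists, and it called 2 of 1108 unshifted lists. These simulations drew genes independently, so they do not cover the correlation between genes.

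Alternatives set before the data were examined were the authors' values, no background correction, median scaling, normalization without the controls, other filters on dim genes, the mean of a gene's probes, array weights, only the groups compared, the replicate number as a block, and leaving out each array of the smallest groups. Leaving out the 2 dim arrays and adding brightness (log2 of the 75th percentile of signal) as a covariate were added after the data were seen, as were leaving out each compared tumour in turn for the called lists, the collagen genes without young unirradiated replicate 2 and the heat shock list without Cryab and Hspb1. Other splits of the samples were drawn 100 times with a fixed seed, and the 1000 simulations behind the correlation between comparisons used unchanged groups.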

Results

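Lewis lung carcinoma (LLC) is a mouse lung tumour line that grows in mice. Transcript levels were measured in LLC tumours from male mice that were young or middle-aged and that were either unirradiated or exposed to iron ions, a heavy-ion component of space radiation, at 0.2 Gy in each of 5 exposures. The tumours fell into 4 groups: 10 from young unirradiated mice, 8 from young irradiated mice, 7 from middle-aged unirradiated mice and 5 from middle-aged irradiated mice. Young unirradiated mice were the study's reference group, and the study asks how host age and irradiation relate to the tumour's transcripts. A further 6 arrays held RNA of LLC cells as technical controls, 3 in each of 2 batches. Each array carried 45281 probes, of which 34885 were paired with 1 gene symbol and 18 with several, while 10378 were not listed with a gene.

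Between 17329 and 19843 probes were detected on 28 of the 30 tumour arrays. The remaining arrays, young irradiated replicates 6 and 8, were dim, with 11860 and 14828 probes detected and 75th percentiles of unnormalized signal of 91.6 and 102. Young irradiated replicate 2 and middle-aged unirradiated replicate 1 were bright, at 1123 and 863. The mean number of detected probes was 18597 ± 573 (SD, n = 10) in young unirradiated, 17180 ± 2511 (SD, n = 8) in young irradiated, 18310 ± 625 (SD, n = 7) in middle-aged unirradiated and 19233 ± 498 (SD, n = 5) in middle-aged irradiated tumours. The number of arrays limits the precision of every comparison. The series text calls the tumours biological replicates, and no source used here says whether each came from a separate animal, so p-values measure the spread between these samples.

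**Figure D1:**
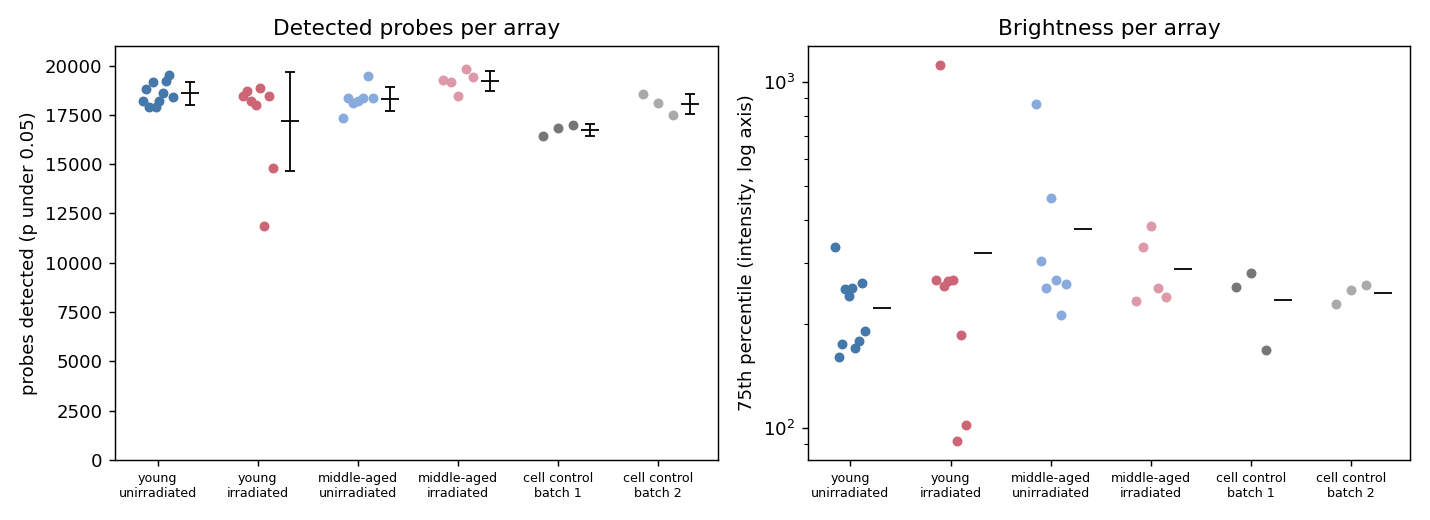
Probes detected per array (left) and 75th percentile of unnormalized signal per array on a log axis (right), 1 point per array. Horizontal lines are group means and bars on the left are SD; young irradiated replicates 6 and 8 lie lowest in both plots, at 11860 and 14828 detected probes.

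Tumours were first set against LLC cells, to show which transcripts the tumour tissue holds beside those of the line. The 12 largest rises were genes of blood, macrophages and connective tissue. The haemoglobin gene Hbb-bt was at least 238-fold higher and Hba-a1 at least 205-fold higher, Lyz2 (lysozyme of myeloid cells) at least 192-fold, Laptm5 (a lysosomal protein of blood cells) at least 139-fold and Lum (lumican, a matrix proteoglycan) at least 115-fold. The complement genes C1qb and C1qc were at least 80.5-fold and 68.6-fold higher, Arg1 (arginase, made by some macrophages) at least 80.7-fold and Fcer1g (an Fc receptor chain) at least 78.4-fold. Lyz1, detected on 6 of 6 cell arrays, was higher by 7.18 on the log2 scale (SE 0.33). Dcn (decorin) and Hbb-bs were detected on only 2 and 1 of the 6 cell arrays, so their differences of 8.37 and 8.44 rest on cell values mostly at background. Every one of these 12 genes was brighter in 30 of 30 tumours than on every cell array and passed limma's test, with adjusted p of at most 2.4e-09.

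Macrophage markers rose together in the tumours: 18 of 23 measured members were higher, 0 lower and 5 did not pass, and 20 were higher when adjusted over the list alone. Antigen presentation rose too, with 8 of 9 class II members higher (8 adjusted over the list alone), such as Cd74 (at least 34.6-fold) and H2-Ab1 (at least 20.1-fold). Of 12 class I members 10 were higher (12 adjusted over the list alone), among them H2-Q7 by 2.35 (SE 0.39, detected on 2 of 6 cell arrays) and H2-K1 by 2.61 (SE 0.45). Inflammatory cytokines were higher for 12 of 15 (12 adjusted over the list alone), with Ccl4 at least 26.3-fold higher and Ccl7 higher by 3.46 (SE 0.45). Of 22 interferon-response genes 15 were higher (18 adjusted over the list alone), with the antiviral genes Oasl2 and Rsad2 at least 12.3-fold and 19.9-fold higher. Endothelial markers were higher for 11 of 19 (12 adjusted over the list alone), with Esam at least 15.3-fold and Robo4 at least 8.26-fold higher. Of 22 fibroblast and collagen genes 9 were higher and 1 was lower, with the same counts adjusted over the list alone. Neutrophil markers were higher for 4 of 15 (7 adjusted over the list alone), such as S100a8 (at least 64.9-fold) and Mmp9 (log2 3.25, SE 0.56, detected on 4 of 6 cell arrays). Of 7 red blood cell markers only Hba-a1 was higher and 0 were lower (1 adjusted over the list alone), with Alas2, at least 5.86-fold higher, next and not passing, and the list median of 0.23 turned to -0.17 with the authors' values. Of 18 skeletal muscle markers 0 passed limma's test, over all genes or adjusted over the list alone, Eno3 (-0.76, SE 0.48) and Tnni2 (at least 3.48-fold higher) having the smallest p.

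Proliferation genes were lower in the tumours than in the cells. The tumours also held transcripts of blood, macrophages and connective tissue, so a lower level need not be a change within the LLC cells. Of 26 cell cycle genes 20 fell and 0 rose (22 lower adjusted over the list alone), including Aurkb (a mitotic kinase), which fell by 1.22 (SE 0.21), and Mcm5 (a replication licensing factor), which fell by 1.13 (SE 0.21). Of 22 DNA repair genes 6 fell and 0 rose (7 lower and 1 higher adjusted over the list alone), with the mismatch repair gene Msh6 lower by -0.82 (SE 0.15) and H2ax by -0.80 (SE 0.20). The largest falls were Adh7 (an alcohol dehydrogenase, log2 -3.99, SE 0.45), Tinagl1 (-3.44, SE 0.70), Slco4a1 (an organic anion transporter, -3.41, SE 0.64) and Atp1b1 (a sodium pump subunit, -3.08, SE 0.40). Foxa2, an endoderm transcription factor, was undetected on all 30 tumour arrays and at least 4.84-fold lower. Atp1b1 was detected on 7 of 30 tumour arrays, Tinagl1 on 19 and Adh7 on 22. Rasl11a (-2.83, detected on 7 of 30 tumours), Id1 (an inhibitor of differentiation, -2.73), Klrg2 (-2.42), Amotl2 (-2.39, detected on 13 of 30), Epop (-2.38), Nrn1 (-2.35) and Tmem158 (-2.35) were the next largest falls. The directions of the other list medians named in this comparison stayed the same under the authors' values, without background correction and under median scaling, where the median of all genes was -0.35.

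Over all 11105 genes tested, limma called 2304 between the 30 tumours and the cells, 1303 higher and 1001 lower, against 3663 at an unadjusted p under 0.05. Of the genes called higher, 417 were over 4-fold and 321 were not detected on any cell array. The cell arrays entered as 1 sample assumed to vary like the tumours, so the test says nothing of the spread between cell cultures, and median scaling lowered the count of calls to 564. Another probe of Hbb-bt was detected on 2 cell arrays, and probes of near-identical haemoglobin and lysozyme genes can share signal. The 12 lists given here, and the number of members named from each, were chosen after their results were seen; of the lists not described for tumours against cells, 16 in number with 234 members, 30 members were higher and 7 lower.

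**Figure D2:**
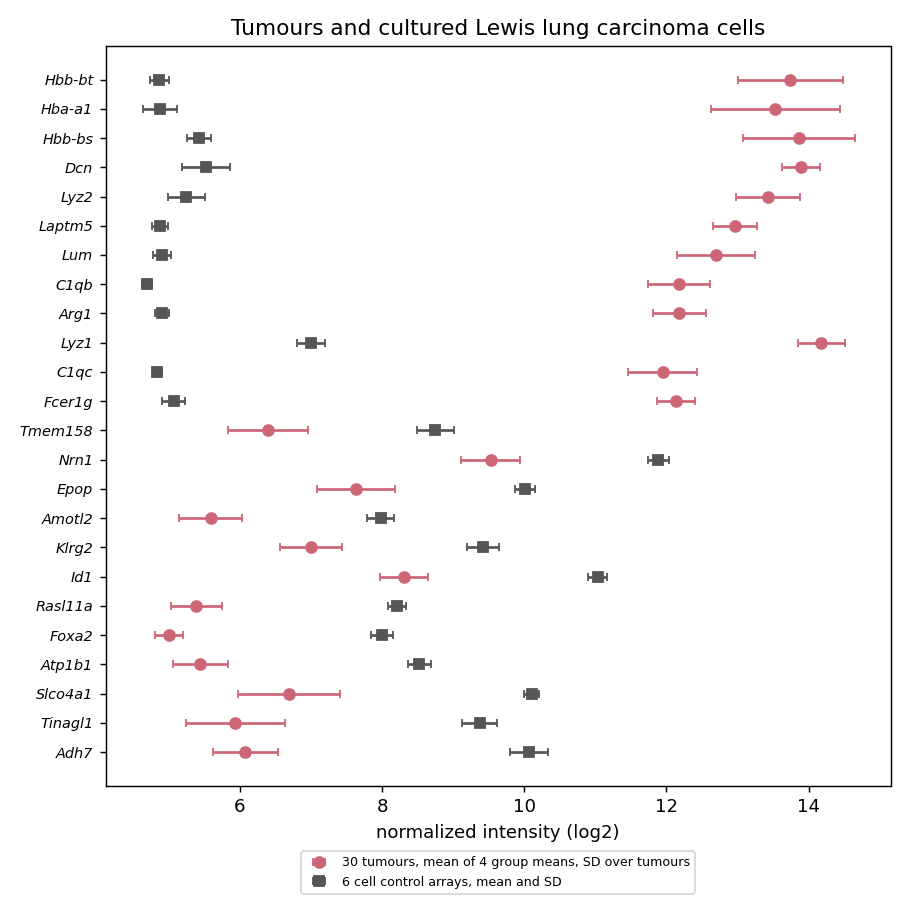
Normalized log2 intensity of the 12 genes with the largest rise and the 12 with the largest fall in tumours against LLC cells. Circles are the mean of 4 group means with the SD over 30 tumours, squares the mean and SD of 6 cell control arrays; Dcn lies 8.37 log2 units higher in tumours and Adh7 3.99 lower, a difference of -3.99.

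Host age was compared in unirradiated mice, with 7 middle-aged and 10 young tumours. Skeletal muscle transcripts were lower as a list in the middle-aged tumours, with a median log2 difference of -1.37 and 18 of 18 members below 0. Neither this list call nor any other of the 7 with age in unirradiated mice holds with an estimated correlation (adjusted p = 0.805 with an estimated correlation for each). Muscle list members with the smallest p were Myl1 and Acta1, a myosin light chain and skeletal actin, at -2.50 (SE 1.35) and -2.60 (SE 1.46), Tcap (titin-cap) at -1.59 (SE 0.88) and the fast myosin Myh4, undetected on all 7 middle-aged arrays and at least 1.34-fold lower. Other detected probes gave smaller falls, -0.76 and -1.28 for Myl1 and -0.88 for Tcap. The mean log2 intensity of the muscle list was 9.01, 11.10 and 11.17 in 3 young unirradiated tumours, 11.03 in 1 young irradiated tumour, 8.33 and 9.46 in 2 middle-aged irradiated tumours and at most 7.04 in the middle-aged unirradiated tumours. Neutrophil markers lay lower in middle-aged tumours, with a median of -0.55 and 15 of 15 members below 0, including the protease Mmp9 (-0.62, SE 0.27), the decoy receptor Il1r2 (-0.80, SE 0.36), Stfa2 (-0.54, SE 0.28) and Csf3r (-0.62, SE 0.33).

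Endothelial markers were lower with age, with a median of -0.31 and 17 of 19 members below 0 (adjusted p = 0.805 with an estimated correlation, as for each list that follows here). The VEGF receptor Flt1 (-0.51, SE 0.15) and the transcription factor Sox18 (-0.79, SE 0.24) passed adjusted over the list alone (2 of 19 members, adjusted p 0.0241), and Esam (-0.42, SE 0.15) and Robo4 (-0.41, SE 0.16) did not. Heat shock proteins were lower (median -0.35, 11 of 13 below 0), with Hsp90aa1 at -0.42 (SE 0.17), Cryab at -1.08 (SE 0.45), Dnajb1 at -0.35 (SE 0.15) and Hspb1 at -0.99 (SE 0.43). Hspb1 was highest of each young group in unirradiated replicate 8 (9.37) and irradiated replicate 1 (8.53), whose muscle list means were 11.17 and 11.03, and at most 7.26 in the other unirradiated tumours, of which replicate 7 had a muscle mean of 11.10. Without Cryab and Hspb1, left out after the values were seen, the heat shock median was -0.25 (adjusted p = 0.0486). Cell cycle genes were lower by a small median of -0.12 (18 of 26 below 0), with Nusap1 (a spindle protein, -0.41, SE 0.12) passing adjusted over the list alone (1 of 26, adjusted p 0.0431), beside Tpx2 (-0.58, SE 0.19), Pcna (-0.66, SE 0.24) and Cdc6 (-0.47, SE 0.18). Hypoxia-response genes were lower (median -0.15, 16 of 19 below 0), with Vegfa at -0.64 (SE 0.29), Ankrd37 at -0.58 (SE 0.27), Adm at -1.03 (SE 0.51) and the glucose transporter Slc2a1 at -0.38 (SE 0.18). MHC class I genes were higher (median 0.25, 11 of 12 above 0), with Tapbp at 0.46 (SE 0.20), the immunoproteasome subunits Psmb8 at 0.59 (SE 0.33) and Psmb10 at 0.20 (SE 0.14), and B2m at 0.38 (SE 0.15). Psmb10 and B2m turn to -0.12 and -0.41 under median scaling, where the median of all genes was -0.07, and B2m to -0.05 with the authors' values. Lists of bright genes fell under that scaling too, to -0.97 for cytosolic ribosomal proteins, -0.41 for glycolysis and -0.33 for oxidative phosphorylation. The reversals of Psmb10 and B2m, also bright, need not be particular to them.

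Camera with its preset correlation gave adjusted p over 34 lists of 0.000292 for muscle, 0.00334 for neutrophil, 0.00334 for endothelial, 0.00700 for MHC class I, 0.00700 for heat shock, 0.0237 for cell cycle and 0.0493 for hypoxia. Over all genes 0 list members passed, and adjusted over the list alone 0 members of the muscle, neutrophil, heat shock, hypoxia and MHC class I lists did; 10 genes of lists that were not called passed that way. The hypoxia call ended without the dim arrays (adjusted p = 0.0601), which are not in this comparison and left the median at -0.15, and with brightness as a covariate (adjusted p = 0.374), where the median was -0.13.

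Relative to all genes under median scaling, the age medians were larger for cell cycle (-0.31), hypoxia (-0.44) and heat shock genes (-0.62) and smaller for endothelial markers (-0.20). Lists that were not called moved on that scale too. Cytosolic ribosomal proteins went from -0.10 to -0.90 and pericyte and smooth muscle markers from -0.07 to 0.09, so such shifts are not particular to the called lists. The authors' values gave -0.21 for cell cycle, -0.30 for hypoxia, -0.21 for endothelial, -0.34 for neutrophil and 0.14 for MHC class I genes. Without background correction the medians were -0.13 for endothelial, -0.29 for neutrophil and -0.82 for muscle markers.

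Each of the 17 tumours was also left out in turn, a check chosen after the calls were seen. The cell cycle call ended without young unirradiated replicate 1 or 2 (adjusted p up to 0.129, median -0.10 in each case). The MHC class I call ended without middle-aged replicate 3 (0.182, median 0.14) or young replicate 1 (0.0513, median 0.21), and without middle-aged replicate 6 its median was 0.38. The hypoxia call ended without middle-aged replicate 2 (median -0.08) or 3 (-0.12) or without young replicate 1, 2, 4, 5 or 10 (medians from -0.16 to -0.12). Muscle, neutrophil, endothelial and heat shock calls stayed at or under an adjusted p of 0.0272, with a muscle median of -0.87 without young replicate 8.

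Of 10907 genes tested with age in unirradiated mice, limma called 0, with 1501 at an unadjusted p under 0.05 against 545 expected by chance. The genes with the smallest p, none of which passed (limma adjusted p = 0.131 for each), were Akr1b10 (an aldo-keto reductase, log2 0.44, SE 0.09), Ankrd66 (at least 1.05-fold higher) and Npnt (nephronectin, 0.57, SE 0.13) on the higher side. On the lower side they were Zmpste24 (the protease that processes lamin A, -0.39, SE 0.08, other detected probes 0.21 and -0.21), Klhl17 (-0.56, SE 0.12) and the ribosomal protein gene Rps3a1 (-0.59, SE 0.13). Limma with array quality weights, which gave the dim arrays weights of 0.142 and 0.278, called 413 genes, 113 higher and 300 lower. Without the dim arrays it called 29, of which 28 were among the 413, and with the authors' values it called 1.

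**Figure D3:**
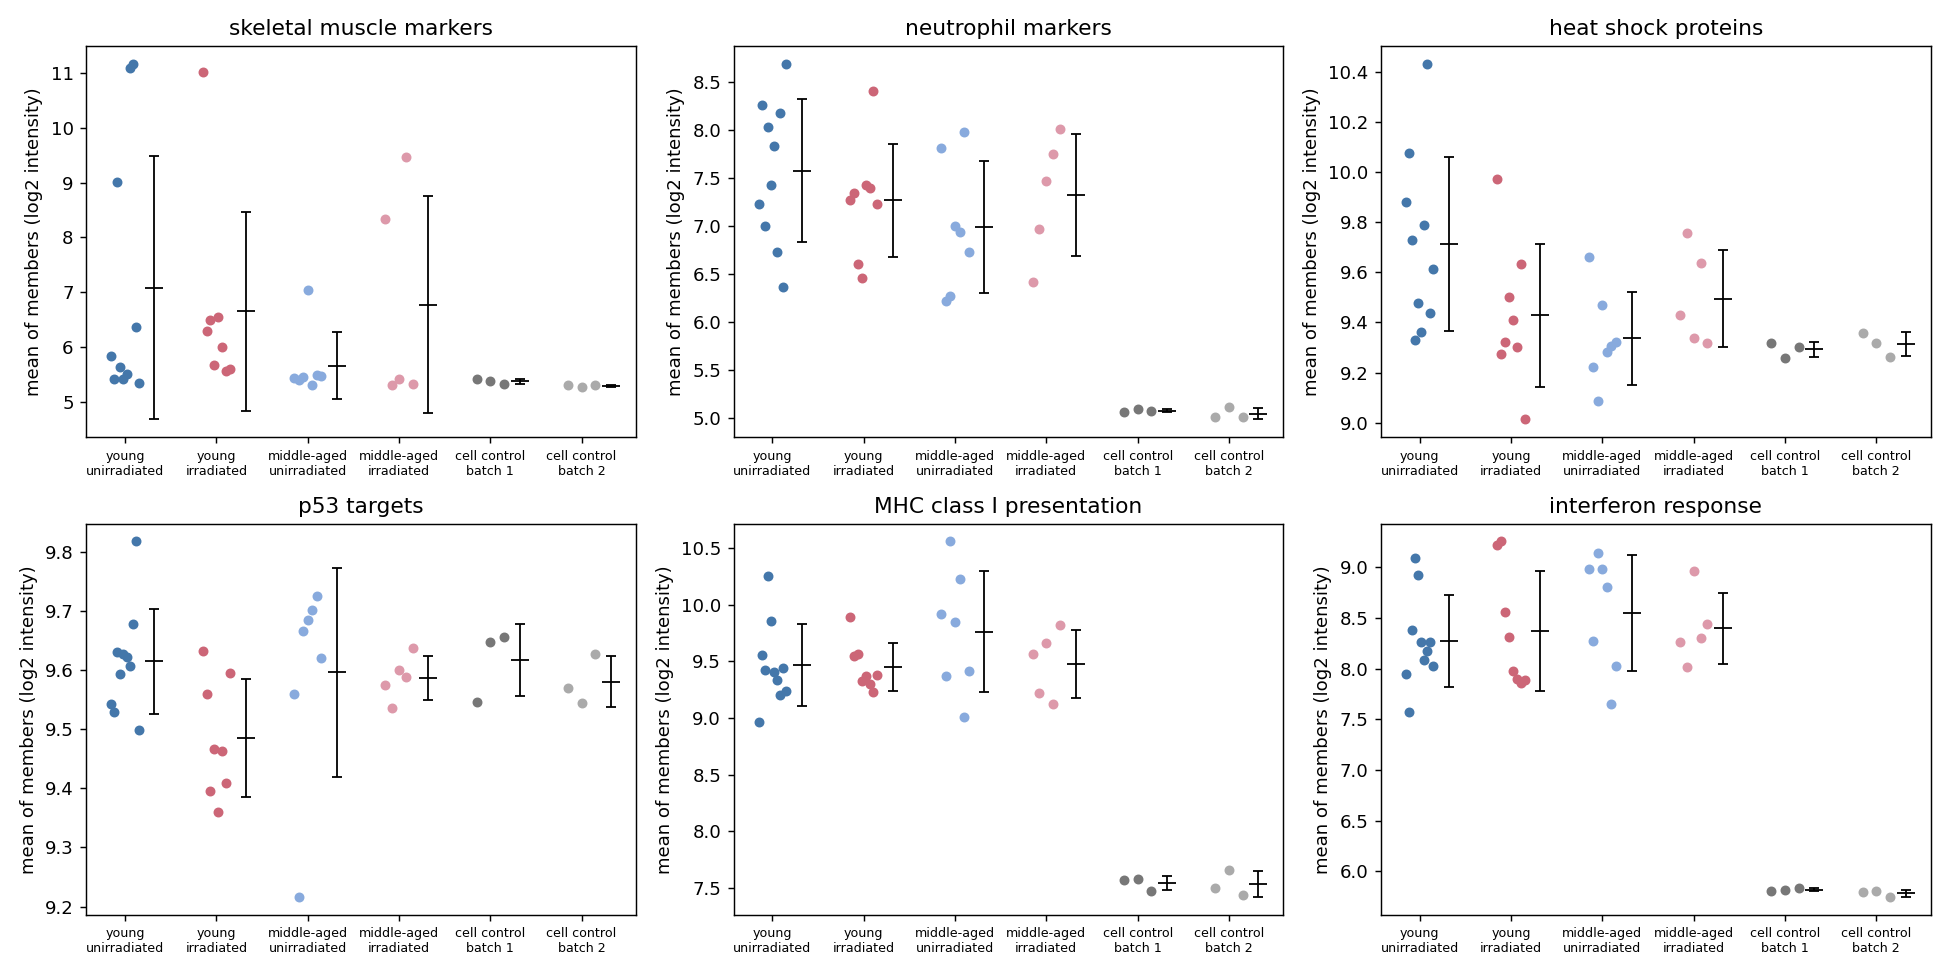
Mean normalized log2 intensity of the members of 6 gene lists, 1 point per array, with group means and SD bars. In the muscle list 3 young unirradiated tumours (9.01, 11.10 and 11.17) stand above the other tumours of their group, and in the neutrophil, MHC class I and interferon lists the cell controls lie below every tumour.

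Irradiation was compared in young mice, with 8 irradiated and 10 unirradiated tumours. These unirradiated tumours are the young ones of the age comparison, so results shared with it are not independent. None of the 5 list calls here holds with an estimated correlation: adjusted p = 0.767 with an estimated correlation for heat shock and p53 targets and adjusted p = 0.855 with an estimated correlation for the others. Collagen and fibroblast genes lay lower in irradiated tumours, with a median of -0.15 and 18 of 22 members below 0, led by Col1a1 (-1.18, SE 0.45), Fbln2 (-1.08, SE 0.48), Bgn (-0.59, SE 0.31) and Col1a2 (-1.06, SE 0.55). Unirradiated replicate 2 had a list mean of 11.55 against at most 10.57 in the other tumours of its group. Without it, a check chosen after the data were seen, the differences were -0.81 for Col1a1, -0.70 for Fbln2, -0.35 for Bgn and -0.60 for Col1a2, and the collagen call ended (adjusted p = 0.0931). Targets of p53 were lower (median -0.14, 17 of 19 below 0), among them Mdm2, the p53 ubiquitin ligase (-0.24, SE 0.09), the cell cycle inhibitor Cdkn1a (-0.27, SE 0.12), Ercc5 (-0.30, SE 0.14) and Polk (-0.25, SE 0.12). Heat shock proteins were lower (median -0.20, 11 of 13 below 0), with Dnajb1 at -0.36 (SE 0.14), Hsph1 at -0.42 (SE 0.21), Hspa1b at -0.53 (SE 0.34) and Cryab at -0.63 (SE 0.43); without Cryab and Hspb1 the median was -0.16 (adjusted p = 0.0294). Red blood cell markers were lower (median -0.62, 7 of 7 below 0), with Hba-a1 at -0.62 (SE 0.38), the membrane anion exchanger Slc4a1 at -1.24 (SE 0.79), Hbb-b2 at -0.64 (SE 0.37) and Klf1 at -0.44 (SE 0.29). Interferon-response genes were higher (median 0.14, 15 of 22 above 0), with Ifi27l2a at 0.64 (SE 0.29), Oas2 at 0.60 (SE 0.32), Ifit2 at 0.44 (SE 0.23) and Oas3 at 0.33 (SE 0.21).

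Under median scaling the median of all genes in this comparison was -0.49, and the interferon median turned to -0.36 there, which is 0.14 above all genes, while Ifi27l2a and Ifit2 turned to -0.06 and -0.16. Hspa1b, Cryab and Klf1 turned to 0.14, 0.08 and 0.15 relative to all genes. Relative to all genes the red blood cell median was only -0.01 under that scaling, and those of collagen, heat shock and p53 genes were larger (-0.34, -0.33 and -0.27). Lists that were not called moved as well on that scale. Oxidative phosphorylation went from 0.02 to -0.24 and T and NK cell markers from 0.03 to 0.34, so such shifts are not particular to the called lists. Without background correction the medians were -0.27 for red blood cell markers, -0.08 for p53 targets and 0.09 for interferon genes, which had 0.07 with the authors' values, and array weights gave -0.09 for collagen genes. Camera's adjusted p was 0.0266 for heat shock, 0.0291 for p53 targets, 0.0291 for collagen, 0.0294 for red blood cell and 0.0405 for interferon. Over all genes 0 members of these lists passed, and adjusted over the list alone 0 did. In lists that were not called, Cldn7 and Tgfb2 (both lower) passed adjusted over the list alone, named after their values were seen. The dim arrays are both in the irradiated group, and without them camera called 12 lists and the interferon median was 0.33. With brightness as a covariate all 5 calls ended (adjusted p from 0.0510 to 0.213) while the medians stayed about as large, at -0.18 for heat shock, -0.15 for p53, -0.13 for collagen, -0.63 for red blood cell and 0.12 for interferon genes.

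Each of the 18 tumours was left out in turn as well. Interferon genes lost their call without irradiated replicate 1 (adjusted p = 0.566, median 0.05), 2 (0.696, median 0.07), 3 or 4 or without unirradiated replicate 2 (0.207, median 0.08), 1, 6, 7, 8 or 10. Their median was 0.25, 0.26 and 0.23 without irradiated replicate 7 and unirradiated replicates 4 and 5. The collagen call ended without irradiated replicate 1 (0.205, median -0.13), 2 (0.172, median -0.09), 3 or 4 or without unirradiated replicate 2, 7 or 10 (medians from -0.18 to -0.09 over these 7). The red blood cell call ended without irradiated replicate 1, 2, 3, 4, 5 or 8 or unirradiated replicate 2, 8 or 10 (adjusted p up to 0.256, medians from -0.65 to -0.43). Heat shock genes lost theirs without irradiated replicate 2, 3 or 4 or unirradiated replicate 2 or 8 (up to 0.0937, medians from -0.22 to -0.15). Targets of p53 lost theirs without irradiated replicate 2, 3, 4, 5 or 7 or unirradiated replicate 8 (up to 0.0897, medians from -0.21 to -0.11).

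Of 10907 genes limma called 0 with irradiation in young mice, with 604 at an unadjusted p under 0.05 against 545 by chance, and it called 0 with array weights and 0 without the dim arrays. The smallest p values, none passing, belonged to Klhl18 (-0.60, SE 0.12, limma adjusted p = 0.105), Slitrk5 (-1.17, SE 0.23, 0.105) and Pdzrn3 (-1.20, SE 0.26, 0.277) on the lower side. Tspyl3 (0.50, SE 0.13), Cyrib (0.34, SE 0.09, but -0.38 on its other detected probe) and Ndst2 (0.31, SE 0.09) followed on the higher side with limma adjusted p of 0.693, 0.693 and 0.773, and Cyrib and Ndst2 turned to -0.20 and -0.31 under median scaling, which is 0.29 and 0.18 relative to all genes.

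Irradiation was then compared in middle-aged mice, with 5 irradiated and 7 unirradiated tumours. Immediate early genes, which respond to growth factors and stress within minutes, were lower in irradiated tumours, with a median of -0.33 and 14 of 17 members below 0. Neither this list call nor either of the other 2 of this comparison holds with an estimated correlation (adjusted p = 0.953 with an estimated correlation for each). Junb (-0.65, SE 0.23) and Jun (-0.43, SE 0.16), subunits of the AP-1 factor, led with Ccn1 (-1.16, SE 0.52, other detected probes -0.71 and -0.51) and Zfp36 (-0.61, SE 0.36). MHC class I genes were lower (median -0.31, 12 of 12 below 0), with H2-T23 at -0.46 (SE 0.27), H2-Q7 at -0.39 (SE 0.23), Tapbp at -0.34 (SE 0.24) and H2-D1 at -0.28 (SE 0.21). These counts use the brightest probe of each gene; other detected probes gave 0.19 and -0.44 for H2-T23 and -0.11 and 0.13 for H2-D1. Skeletal muscle transcripts were higher (median 1.12, 18 of 18 above 0), with Mybpc2 at 1.54 (SE 1.12), Actn3 at 0.94 (SE 0.73), Tnnc2 at 1.68 (SE 1.35) and the calcium channel Ryr1 at least 1.25-fold higher. The muscle list mean was 8.33 and 9.46 in 2 of the 5 irradiated tumours and at most 5.42 in the other 3. The unirradiated tumours here are also those of the age comparison. Their MHC class I list mean was 9.76 ± 0.54 (SD, n = 7). It was 9.47 in young unirradiated, 9.45 in young irradiated and 9.48 in middle-aged irradiated tumours. For muscle the mean was 5.65 in this group and 7.08, 6.65 and 6.77 in those groups. The MHC class I and muscle calls with age and with irradiation here are therefore not independent results.

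Camera's adjusted p was 0.00273 for immediate early genes, 0.00842 for MHC class I and 0.00842 for muscle. The muscle call ended without middle-aged irradiated replicate 1 (adjusted p = 0.172, median 0.78) or 4 (0.616, median 0.50), and the MHC class I call without irradiated replicate 4 (0.214, median -0.18) or unirradiated replicate 3 (0.282, median -0.19) or 5 (0.0778, median -0.20). Over all genes 0 of their members passed, and adjusted over the list alone 0 did. Under median scaling the median of all genes was 0.29 here, and the MHC class I median turned to 0.07, or -0.23 relative to all genes, and H2-D1 to 0.29, level with all genes. With array weights the immediate early and muscle calls ended (adjusted p = 0.132 and 0.0972) while their medians stayed about as large (-0.24 and 1.00). The authors' values gave medians of -0.17 for immediate early, -0.17 for MHC class I and 0.66 for muscle genes, and no background correction gave 0.59 for muscle.

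Limma called 0 of 10907 genes with irradiation in middle-aged mice, with 690 at an unadjusted p under 0.05 against 545 by chance, and with array weights it called 227, 147 higher and 80 lower. Closest to passing were Arl1 (a Golgi GTPase, 0.63, SE 0.13), the nucleosome-binding gene Hmgn5 (0.88, SE 0.19) and Cap1 (an actin regulator, 0.62, SE 0.15) on the higher side, and none passed. Olfr538 (-0.75, SE 0.16), Atp6v1g1 (a proton pump subunit, -0.58, SE 0.14) and Dohh (-0.57, SE 0.15) were closest on the lower side, and limma's adjusted p ran from 0.285 to 0.589 over these 6 genes.

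Middle-aged and young mice were also compared among irradiated tumours, 5 against 8. Nbas, a gene of transport between Golgi and endoplasmic reticulum, was higher in the middle-aged tumours by 0.76 on the log2 scale (SE 0.13) and was detected on all 5 of them and on none of the 8 young irradiated arrays; 5 of 5 lay above all 8. Its bound against the detection limit is under 1, so no fold is given. Limma called this 1 gene of 10907 (adjusted p = 0.0435), with 797 at an unadjusted p under 0.05 against 545 by chance. The call ended with a smaller difference for the mean of the gene's probes (0.24, adjusted p = 0.638), the authors' values (0.26, 0.465) and no background correction (0.26, 0.274). It also ended while the difference stayed about as large, without the dim arrays (0.71, adjusted p = 0.0868) and when any 1 of the 5 middle-aged irradiated tumours was left out (0.71 to 0.81, 0.0555 to 0.255). Under median scaling it ended at a difference of 0.76 (0.0683), only 0.05 relative to all genes against 0.74 with quantile normalization. Over all alternatives the adjusted p ran from 0.00763 to 0.638.

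No list was called with age among irradiated tumours: camera gave 0 of 34 with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.989) and fry's directional test gave 0 (smallest 0.760). The smallest camera adjusted p, 0.0940, belonged to cell cycle genes (median -0.08) and to collagen and fibroblast genes (median 0.20), and median scaling, under which the median of all genes was 0.71 here, gave a cell cycle median of 0.76, or 0.05 relative to all genes, and a collagen median of 1.02, or 0.31 relative to all genes. Without the dim arrays camera called 4 lists. Adjusted over the list alone, 5 genes passed: Aurkb and Ccna2 of the cell cycle (lower), the integrins Itga2 and Itgb1 (higher) and Pdia4 of the unfolded protein response (higher), all chosen after their values were seen.

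Middle-aged irradiated tumours were set against the reference group of young unirradiated tumours, 5 against 10. Hmgn5 was 2.21-fold higher, a log2 difference of 1.14 (SE 0.18, limma adjusted p = 0.00609), and 5 of 5 middle-aged irradiated tumours lay above all 10 reference tumours. Its mean log2 intensity was 8.77 in young unirradiated, 9.01 in young irradiated, 9.04 in middle-aged unirradiated and 9.92 in middle-aged irradiated tumours. Nbas was at least 1.16-fold higher (limma adjusted p = 0.0218), detected on 5 of 5 middle-aged irradiated arrays and none of the 10 reference arrays. The second Nbas probe did not pass the detection filter. The Nbas call ended with a smaller difference for the mean of probes (0.35, adjusted p = 0.701), the authors' values (0.26, 0.484) and no background correction (0.24, 0.179). Under median scaling it ended at a difference of 0.74 (0.0750), or 0.55 relative to all genes.

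Limma called these 2 genes of 10907, with 647 at an unadjusted p under 0.05 against 545 by chance, and it called 32 with array weights (26 higher, 6 lower) and 8 without the dim arrays, all 8 among the 32. The Hmgn5 call ended under median scaling (adjusted p = 0.141, difference 1.42, or 1.23 relative to all genes) and without middle-aged irradiated replicate 1 (0.0707, 1.07) or 2 (0.0763, 1.06). The Nbas call ended without replicate 1 (0.144, 0.68), 2 (0.141, 0.71) or 3 (0.156, 0.71), differences about as large as with all tumours. Over all alternatives the adjusted p ran from 0.000478 to 0.141 for Hmgn5 and from 0.000930 to 0.701 for Nbas. Camera called 0 of 34 lists with the preset and 0 with an estimated correlation (smallest adjusted p = 0.949), and fry's directional test 0 (smallest 0.831). The lists nearest to passing were red blood cell markers (median -0.94, 6 of 7 below 0) and NRF2 targets (median -0.23, 17 of 21 below 0), each with a camera adjusted p = 0.0611. Itga2 and Itgb1 again passed adjusted over the list alone (2 of 19 integrin and adhesion genes, higher), a choice made after their values were seen.

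Whether irradiation acted differently at each age was tested as the difference between the irradiation effects in middle-aged and in young mice, written as middle-aged minus young. It uses the same 4 groups, so its calls are not independent of those in the comparisons above. None of the 6 list calls holds with an estimated correlation (adjusted p = 0.831 with an estimated correlation for each). Muscle transcripts differed most, with a median of 1.61 and 18 of 18 members above 0, among them Actn3 (1.47, SE 0.94), Tcap (1.84, SE 1.35), creatine kinase Ckm (2.28, SE 1.68) and Myh4 (1.62, SE 1.22). Neutrophil markers (median 0.59, 14 of 15 above 0) included Chil3 (1.57, SE 0.75, other detected probes 1.28 and 0.05), Retnlg (1.62, SE 1.01), Ngp (0.67, SE 0.44) and Il1r2 (0.71, SE 0.55). Heat shock proteins (median 0.34, 11 of 13 above 0) included Cryab (1.49, SE 0.69), Dnajb1 (0.46, SE 0.22), Hspb1 (1.25, SE 0.66) and Hspd1 (0.21, SE 0.14, other detected probe -0.06). On the lower side stood fatty acid and cholesterol synthesis (median -0.29, 12 of 16 below 0) with Elovl6 (-0.52, SE 0.22), Fdps (-0.52, SE 0.24), Srebf2 (-0.52, SE 0.32, other detected probe 0.07) and Sqle (-0.34, SE 0.25). Interferon-response genes (median -0.30, 16 of 22 below 0) were led by Oas2 (-1.06, SE 0.50), Oas3 (-0.53, SE 0.33), Ifi27l2a (-0.64, SE 0.46) and Irf9 (-0.31, SE 0.24, other detected probe 0.12), and MHC class I genes (median -0.25, 11 of 12 below 0) by Tap1 (-0.62, SE 0.39), H2-T23 (-0.52, SE 0.34, other detected probes 0.05 and -0.55), H2-D1 (-0.36, SE 0.27) and H2-Q7 (-0.33, SE 0.29).

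Camera's adjusted p was 0.00478 for muscle, 0.0125 for fatty acid synthesis, 0.0125 for heat shock, 0.0209 for interferon, 0.0209 for MHC class I and 0.0318 for neutrophil markers. The heat shock call ended without Cryab and Hspb1 (adjusted p = 0.0704, median 0.28). Over all genes 0 of their members passed, and adjusted over the list alone 0 did. Under median scaling the median of all genes was 0.78 in this contrast, and the medians of the 3 lower lists turned to 0.64, 0.47 and 0.67, or -0.14, -0.31 and -0.11 relative to all genes. On that scale muscle had 1.02, neutrophil 0.20 and heat shock genes 0.58, while single members reversed: Sqle to 0.15, H2-D1 to 0.25 and Ngp to -0.07. The MHC class I call ended without the dim arrays (adjusted p = 0.0711), where its median was larger (-0.32), and array weights gave it -0.40. With brightness as a covariate the fatty acid (0.0694, median -0.21), MHC class I (0.0887, -0.19) and neutrophil (0.126, 0.51) calls ended with medians about as large, and the interferon call (0.287) with a smaller median of -0.10. The authors' values gave medians of -0.13 for fatty acid, -0.15 for interferon, -0.13 for MHC class I, 0.25 for neutrophil and 1.07 for muscle genes. Without background correction they were 0.25 for neutrophil and 0.98 for muscle markers.

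Leaving out 1 of the 30 tumours at a time ended the muscle call for middle-aged irradiated replicate 4 (adjusted p = 0.164, median 1.01), the fatty acid call for middle-aged unirradiated replicate 1 (0.0508, median -0.20) and the heat shock call for middle-aged irradiated replicate 2 (0.0529, median 0.28). The interferon call ended without middle-aged unirradiated replicate 1 (median -0.19), 3 (-0.16) or 4, middle-aged irradiated replicate 2 or 4, young irradiated replicate 1 (-0.17) or 2 (-0.12, adjusted p = 0.236) or young unirradiated replicate 1 or 2 (-0.17). For MHC class I these were middle-aged irradiated replicates 2 and 4 (median -0.11), middle-aged unirradiated replicates 1, 3 (-0.11, adjusted p = 0.238) and 5, young irradiated replicate 1 and young unirradiated replicate 1. Neutrophil markers lost their call without middle-aged irradiated replicate 4 or 5 (0.37, adjusted p = 0.237), middle-aged unirradiated replicate 2 (0.36), 3 (0.38), 4 or 7, young irradiated replicate 1, 2, 3 or 4 or young unirradiated replicate 2, 4, 5, 6, 8 or 10.

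Limma called 0 of 10907 genes for this difference, with 482 at an unadjusted p under 0.05 against 545 by chance, and 0 with array weights and 0 without the dim arrays. The smallest p values, none passing (limma adjusted p = 0.981 for each), belonged to the glutamate receptor subunit Gria3 (0.79, SE 0.18, but -0.12 relative to all genes under median scaling), Ywhab (0.64, SE 0.16) and the adhesion molecule Ncam1 (1.36, SE 0.35, other detected probes 0.24 and 0.18), and to Ebag9 (-0.88, SE 0.22), Tspoap1 (-1.09, SE 0.31) and Snx15 (-0.56, SE 0.16, which turned to 0.53 under median scaling, or -0.25 relative to all genes). Gria3 was detected on no young irradiated and no middle-aged unirradiated array. Among the list members named for this difference, Myh4 and Ngp were detected on no middle-aged unirradiated array and Oas3 on no middle-aged irradiated array. The values of these genes rest partly on background.

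As a check that treats tumours and not genes as the units, the mean score of each of the 15 lists called in comparisons of 1 group with another was compared by a two-sided exact permutation test, chosen after the calls were seen. The smallest exact p was 0.00999 for p53 targets in young mice, with scores of 9.49 ± 0.10 (SD, n = 8) in irradiated and 9.61 ± 0.09 (SD, n = 10) in unirradiated tumours. Heat shock proteins followed with age in unirradiated mice (exact p = 0.0168), with 9.34 ± 0.18 (SD, n = 7) in middle-aged and 9.71 ± 0.35 (SD, n = 10) in young tumours. After Benjamini-Hochberg adjustment over the 15 tests none passed, the smallest adjusted exact p being 0.126.

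The effects of age and of irradiation in young mice share the same young unirradiated tumours. Across 10907 genes their log2 changes had a Pearson r of 0.112 and a covariance of 0.00568. Unchanged groups simulated against the same tumours gave a mean r of 0.420 (range -0.126 to 0.805) and a covariance of 0.0139, and 89.3% of simulations had an r as large. With the shared tumours split 5 and 5 between the comparisons the mean r was -0.108, and without the dim arrays r was 0.489. Genes are not independent replicates. Heat shock proteins were called in both of these comparisons and in the difference between ages. Their mean score was 9.71 ± 0.35 (SD, n = 10) in young unirradiated and 9.43 ± 0.28 (SD, n = 8) in young irradiated tumours. It was 9.34 ± 0.18 (SD, n = 7) in middle-aged unirradiated and 9.49 ± 0.19 (SD, n = 5) in middle-aged irradiated tumours. Each of these calls uses the young unirradiated group, which had the highest mean, so they are not independent results.

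The batches of LLC cell controls, 3 arrays each, were compared as a technical reference. Detected probes numbered 16420 to 16971 in batch 1 and 17510 to 18546 in batch 2, ranges that do not overlap. Limma called 0 of 9241 genes, with 285 at an unadjusted p under 0.05 against 462 by chance, and 0 without background correction, with median scaling and with the authors' values. Only 2 genes differed by over 2-fold. The median SD within a batch was 0.192 log2 units, against 0.322 within the tumour groups.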

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

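The tests of muscle tissue in the tumour piece (correlation of list members) and of a batch (correlation with the control batch difference) were chosen only after the result was seen.

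Young irradiated replicates 6 and 8 stood apart from the other tumours in brightness and detected probes. Across genes, their deviation from the other 6 young irradiated arrays correlated at r = 0.470 with the change per unit of falling brightness on the other 28 tumours, so low brightness is a candidate explanation. Their difference from unirradiated tumours correlated at a mean r of -0.228 with that of the other 6 irradiated arrays over disjoint controls (range -0.434 to -0.00707). Limma called 0 genes with irradiation in young mice, with or without the dim arrays. With no called response to share, this correlation cannot decide on a shared irradiation response. Why these arrays were dim was not tested, and RNA amount, labelling and hybridisation stay open. A biological difference between these tumours and the others was not tested either.

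Skeletal muscle transcripts were lower in middle-aged unirradiated tumours and higher with irradiation in middle-aged mice, calls of camera that do not hold with an estimated correlation (adjusted p = 0.805 and 0.953 with an estimated correlation). Muscle tissue in the piece of tumour taken may account for this: the 18 list members had a mean residual correlation of 0.903 over the 30 tumours, 15 of the 18 were not detected on any cell array, and the abundant Acta1 and Myl1 averaged 8.54 and 8.31 in young against 5.94 and 5.81 in middle-aged unirradiated tumours. Array brightness is argued against, since the median change stayed at -1.16 with brightness as a covariate. Exact two-sided permutation tests of the list score gave p = 0.162 for age (7 against 10 tumours) and 0.302 for irradiation (5 against 7), so chance between tumours cannot be excluded. Both comparisons use the same 7 middle-aged unirradiated tumours, so they are not independent results. An effect of age on growth into muscle stays open as an untested biological explanation.

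The age effect in unirradiated tumours correlated across 9117 genes with the difference between the batches of cell controls, at r = 0.143. Of 100 splits of the same 17 tumours, 1 gave as large a correlation, the real one, and the highest other was 0.138. A batch that partly follows age is thus a candidate explanation, but the batch difference itself may be mostly noise. Limma called 0 of 9241 genes between the control batches, with 285 at an unadjusted p under 0.05 against 462 by chance. Noise of dim genes is argued against, since r was 0.129 among 6351 genes detected on all 36 arrays. The irradiation effect in young mice had r = -0.0132 with the same difference. No tumour is placed in a batch by the sources used here, so batch and age cannot be separated, and an effect of age stays open. The middle-aged unirradiated tumours carry numbers furthest from those of the other groups. A difference in handling of that group alone can be neither tested nor excluded. The comparisons that include middle-aged irradiated tumours were not set against the control batch difference.

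Samples far from the others of their group were sought by the ratio of the gap to the range, over array measures, called lists and named genes. Of 624 group values tested 58 stood out, where chance gives about 31 (1 in 20 groups), and named genes of 1 list are not independent. Young irradiated replicate 1 was highest for the muscle list (mean log2 11.03, next 6.54) and for Tcap (10.62), Myh4 (9.39), Actn3 (9.54), Ryr1 (9.03), Tnnc2 (12.11), Ckm (11.63), Eno3 (10.29), Tnni2 (12.37) and Hspb1 (8.53). Middle-aged unirradiated replicate 4 was highest for the muscle list (7.04, next 5.49), Myl1 (9.44), Tcap (5.77), Acta1 (9.97), Myh4 (5.04), Mybpc2 (6.08), Tnnc2 (6.99), Ckm (6.75) and Tnni2 (8.56), and lowest for Hmgn5 (8.09, next 9.01). Young unirradiated replicate 2 was highest for the collagen and fibroblast list (11.55, next 10.57), Col1a1 (12.96), Fbln2 (11.97), Bgn (13.16), Col1a2 (11.11) and Pdzrn3 (9.02), and lowest for Dcn (13.18), Lum (10.92) and Ifit2 (7.51). Among other young unirradiated tumours, replicate 6 was highest for Zmpste24 (11.24), replicate 8 for Hspb1 (9.37) and replicate 10 for Klf1 (8.48) and Ngp (7.54).

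Young irradiated replicate 2 was the brightest array of its group (75th percentile 1123, next 268) and lowest for Dcn (13.01) and Lyz1 (12.92). The dim replicate 6 was highest for Tspyl3 (8.28) and lowest for Pcna (5.77), C1qb (11.53), C1qc (11.04) and Epop (5.21). Replicate 7 was highest for immediate early genes (10.49, next 9.50), Csf3r (8.23) and Hbb-b2 (7.12). Middle-aged unirradiated replicate 1 was the brightest of its group (863, next 462) and lowest for Dcn (13.52), replicate 2 was lowest for p53 targets (9.22, next 9.56), Cdkn1a (11.36) and Tspyl3 (6.77), and replicate 6 was lowest for Lyz2 (12.35) and C1qb (10.86). Among middle-aged irradiated tumours, replicate 1 was lowest for Pdzrn3 (6.55) and Srebf2 (9.12), replicate 2 lowest for Mmp9 (8.10), replicate 3 highest for Irf9 (9.42), replicate 4 highest for Atp1b1 (5.93), and replicate 5 lowest for Rps3a1 (11.52) and highest for Hbb-b2 (5.43).

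The irradiation effect differed between ages, by camera with the preset correlation, for skeletal muscle (adjusted p = 0.00478), fatty acid and cholesterol synthesis (0.0125), heat shock proteins (0.0125), interferon response (0.0209), MHC class I (0.0209) and neutrophil markers (0.0318); none holds with an estimated correlation (adjusted p = 0.831 with an estimated correlation).

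Among 3527 probes that are not listed with a gene, 320 were higher and 205 lower in tumours than in LLC cells by limma, and 0 were called in each of the 6 tumour comparisons, where 163 to 432 had an unadjusted p under 0.05.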

How the results depend on the processing

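Leaving out the 2 dim arrays, adding brightness as a covariate, leaving out each tumour for lists, the collagen genes without young unirradiated replicate 2 and the heat shock list without Cryab and Hspb1 were chosen only after the data were seen; the other settings were planned. Age in unirradiated mice (0 genes) gave 1 with the authors' values, 413 with array weights and 29 without the dim arrays, and irradiation in middle-aged mice (0) gave 227 with array weights. Age in irradiated mice (1 gene) gave 3 with the authors' values, 2 without background correction, 4 with median scaling, 0 among genes detected on all arrays, 2 with no filter, 0 with the mean of probes, 6 with array weights, 0 without the dim arrays and 0 with only the groups compared; leaving out 1 middle-aged irradiated tumour gave 0 to 0. Middle-aged irradiated against young unirradiated (2 genes) gave 1 with the authors' values, 1 without background correction, 1 with median scaling, 1 among genes detected on all arrays, 4 with the mean of probes, 32 with array weights, 8 without the dim arrays and 5 with only the groups compared; leaving out 1 tumour gave 0 to 7. Tumours against cells (2304 genes) gave 564 with median scaling and 2066 to 2871 otherwise.

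Called lists numbered 0 with an estimated correlation and 0 with fry's directional test in all 6 comparisons; fry's mixed test, for change in either direction, passed oxidative phosphorylation with age in unirradiated mice (adjusted p = 0.0220). With age in unirradiated mice (7) the authors' values gave 11; with irradiation in young mice (5) array weights gave 11, no dim arrays 12 and brightness 0; with irradiation in middle-aged mice (3) array weights gave 1. With age in irradiated mice (0) array weights gave 3, no dim arrays 4 and brightness 3, for middle-aged irradiated against young unirradiated (0) the authors' values gave 3, and for the difference between ages (6) brightness gave 2. Leaving out 1 tumour gave 4 to 11 lists with age in unirradiated mice, 0 to 9 with irradiation in young mice, 1 to 6 with irradiation in middle-aged mice, 0 to 3 with age in irradiated mice, 0 to 6 for middle-aged irradiated against young unirradiated and 2 to 9 for the difference between ages. The correlation between the age and irradiation effects (0.112) became 0.520 with median scaling and -0.108 with the controls split. In 178 other settings of these counts and values the result stayed within 1.5 times or 1 SD. The cause was not tested, apart from fewer samples or genes where arrays or genes were left out.

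Directions reversed under median scaling: Cyrib -0.20, Ndst2 -0.31, Ifi27l2a -0.0560 and Ifit2 -0.16 with irradiation in young mice, where the median of all genes was -0.49. With age B2m turned to -0.41 and Psmb10 to -0.12, where the median of all genes was -0.07 and that of cytosolic ribosomal proteins -0.97. H2-D1 turned to 0.29 with irradiation in middle-aged mice (all genes 0.29). For the difference between ages (all genes 0.78) the reversed values were Snx15 0.53, Elovl6 0.49, Fdps 0.68, Srebf2 0.50, Sqle 0.94, Ifi27l2a 0.45, Irf9 0.60, H2-T23 0.45, H2-D1 1.03 and H2-Q7 0.36. Relative to all genes only B2m, Psmb10, H2-D1 and Sqle of these were still reversed, H2-D1 in middle-aged mice standing level with all genes. Gria3 (-0.12) and Ngp (-0.07) for the difference between ages, and Hspa1b (0.14), Cryab (0.08) and Klf1 (0.15) with irradiation in young mice, reversed only on that scale. B2m turned to -0.0491 with the authors' values. Among other values of named genes and of the heat shock list 1541 kept direction and side of the threshold, 24 fell below it and 24 passed it.

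No source used here states that replicate numbers pair the tumours. Of 37 same-number pairs 14 had a correlation over 0.1 (mean r 0.04), as had 82 of 294 pairs of different numbers (mean r -0.003). Only 4 of 30 tumours lay closest to one of their own number. Such correlations cannot decide whether the numbers pair animals. With the number as a block, limma called 0 genes with age in irradiated mice (Nbas adjusted p = 0.220) and 0 for middle-aged irradiated against young unirradiated (Hmgn5 0.0674, Nbas 0.0754), and camera called 2 lists with irradiation in young mice, 5 with irradiation in middle-aged mice, 4 with age in irradiated mice and 1 for middle-aged irradiated against young unirradiated. The planned chip block (also for lists) and batch covariate were not run, since no source used here gives a tumour's chip or batch. Signal over background limits the dim arrays, where 11860 and 14828 probes were detected.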

Other observations

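All tests of the array-weight, no-dim-array and unadjusted counts against other splits were chosen only after those counts were seen, although array weights themselves were planned; the counts of other splits for calls of 0, and the leave-one-out checks of lists, were also chosen knowing the real counts.

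Counts of passing members between tumours and LLC cells follow for further gene groups, chosen after their results were seen. No list test was made against the cells, and 2304 of all 11105 genes passed. Of 17 immediate early genes 7 were higher and 0 lower (7 adjusted over the list alone), with Junb higher by 2.20 (SE 0.39) and Klf6 by 1.06 (SE 0.20). Hypoxia-response genes were higher for 6 of 19 (7 adjusted over the list alone), with Ndrg1, a stress-induced gene, higher by 2.57 (SE 0.55) and Ankrd37 by 2.23 (SE 0.55). Of 20 TGF-beta signalling genes 9 were higher and 3 lower, with the same counts adjusted over the list alone, and Tgfbi rose by 3.38 (SE 0.21) while Id1 fell by 2.73 (SE 0.33). Among 14 genes of epithelial-mesenchymal transition 2 were higher and 2 lower (the same adjusted over the list alone), the transcription factors Snai2 and Twist2 falling by 2.14 (SE 0.41) and 1.06 (SE 0.25). The list's median of 0.05 turned to -0.04 with the authors' values and to -0.20 under median scaling, or 0.15 relative to all genes. Apoptosis regulators were higher for 6 of 17 (7 adjusted over the list alone), with the death promoter Bcl2l11 higher by 2.27 (SE 0.22) and Casp9 by 1.85 (SE 0.49); the list's median turned from 0.23 to -0.30 under median scaling, or 0.04 relative to all genes. Of 33 oxidative phosphorylation genes 4 were lower (3 adjusted over the list alone), such as Cyc1 (-0.63, SE 0.17) and Ndufv2 (-0.60, SE 0.16).

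With array weights, several genes chosen here after their values were seen differed with age in unirradiated mice. Thsd4, a matrix protein gene, was higher by 0.91 (SE 0.15, limma adjusted p = 0.00752) and by 0.86 without the dim arrays (adjusted p = 0.0175). Txnrd1, the cytosolic thioredoxin reductase, was lower by -1.09 (SE 0.21, adjusted p = 0.00836) and by -1.10 without the dim arrays (0.0366), and Pam (peptide amidation) by -1.23 (SE 0.23, 0.00836) and by -1.22 (0.0380). In the unweighted fit none of them passed, although Txnrd1 passed adjusted over the list of NRF2 targets alone (adjusted p = 0.00605).

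Other splits of the samples into groups of the same sizes were fitted for each comparison. A real count of 0 genes is matched by every split, 100 of 100, by construction, which says nothing about chance; the highest other count was 2 with age in unirradiated mice, 1 with irradiation in middle-aged mice, 9 for the difference between ages and 2898 with irradiation in young mice. With age in irradiated mice 10 of 100 gave as many as the real 1, so chance cannot be excluded, and the highest other gave 900; splits several times larger than the real count point to a structure of the samples. Of the 3 splits with over 50 calls in young mice (a number chosen after the counts were seen), 2 had both dim arrays on the same side, as had 47 of all 100; of those with age in irradiated mice the 1 such split had both on the same side, as had 50 of 100. These splits are too few to say whether the dim arrays underlie that structure. For middle-aged irradiated against young unirradiated 1 of 100 gave as many as the real 2 genes, the real one (highest other 1). That share rests on a margin of 1 gene and was not adjusted over the 6 comparisons tested, so it does not exclude chance. Leaving out 1 tumour gave 0 to 7 calls. The 10 splits of the 6 control arrays are too few for a share under 0.05 (real 0, highest other 0, as many in 10).

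For lists called with the preset correlation chance cannot be excluded in any comparison with calls: 56 of 100 splits gave as many as the real 7 with age in unirradiated mice (highest other 15), 60 as many as 5 with irradiation in young mice (16), 97 as many as 3 with irradiation in middle-aged mice (14) and 54 as many as 6 for the difference between ages (18). The real 0 with age in irradiated mice (highest other 11) and for middle-aged irradiated against young unirradiated (15) is matched by 100 of 100 splits by construction, which says nothing about chance.

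Some further counts were set against splits because they were large among 6 comparisons and several settings, so a small share among splits does not exclude chance after that choice. With array weights 3 of 100 splits gave as many as the real 413 genes with age in unirradiated mice (highest other 932), and 3 as many as the real 227 with irradiation in middle-aged mice (highest other 596). Without the dim arrays 1 of 100 gave as many as the real 29 with age, the real one (highest other 16). At an unadjusted p under 0.05, 2 gave as many as the real 1501 with age (highest other 1757); this comparison was picked because its count was the largest of the 6. The highest other splits lay above the real count in all of these but the one without the dim arrays.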
